A study of Caenorhabditis elegans with 2 samples.

How the data were processed

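Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where an eGFP-tagged copy of LIN-39, a Hox transcription factor, sat on DNA in whole second-stage (L2) larvae of Caenorhabditis elegans. Per the labels, the worms were of strain OP18, which carries the integrated transgene wgIs18 in an unc-119 mutant background, and the 2 libraries were biological replicates 1 and 2 of 1 group. No second condition, stage or factor was among the samples. The comparisons are therefore between the replicates, and between the peaks and the genome or other regions of the same lists.

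The authors deposited narrowPeak tables on the ce10 and the ce11 genome builds. Per the deposited text files that accompany each library, each replicate's candidate list ("peaks and background") was derived from that replicate's alignments. A further candidate list was derived from both replicates' alignments together, and the optimal list from all 3 candidate lists. IDR, the irreproducible discovery rate, is a method that scores how far the ranks of peaks agree between replicates. The peaks on the optimal list did not all rank high in both replicates. The aligner, the peak caller and the IDR threshold are not given in the sources used here. Every candidate list held exactly 30000 regions, which is a fixed list length and not a measure of occupancy. All regions of a list had 1 width, which on ce11 was 330 bp in replicate 1, 300 bp in replicate 2 and 310 bp in the list from both. Every summit stood at the middle of its region.

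The deposited signal column holds the caller's signal value per region. What it is relative to is not given in the sources used here, so it was never used to compare levels between lists. Within 1 list it was used to rank regions and, in the coverage-factor test on X alone, as a level. The q column that the authors deposited was treated as a score. In narrowPeak it is nominally −log10 of a q-value, but 19118 of the 30000 values in the ce11 list from both replicates lay below 0. No p-value was given in any list. Read counts and sequencing depth are unknown from these tables, so intervals below cover the counting of regions only.

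All coordinates are 1-based on ce11, whose chromosomes have the lengths of the WBcel235 assembly; no ce11 region ended beyond the matching chromosome. Gene models were the 19973 protein-coding genes of Ensembl release 115 on WBcel235 on the 6 nuclear chromosomes, with 29314 distinct 5′ ends of coding transcripts. Annotated 5′ ends in this species often lie downstream of the site where transcription starts, because leaders are trans-spliced. A summit was called promoter-proximal from 1000 bp upstream to 200 bp downstream of a 5′ end. Each peak was assigned to the gene with the nearest 5′ end within 5000 bp of the summit. An assignment names a neighbour and is not evidence that the gene is regulated.

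Peak location was tested against 1000 random placements of the summits on their own chromosomes (two-sided permutation test, smallest possible p 0.002). Peaks per chromosome were tested with exact binomial tests against length. For 19 gene lists, the number of members with a peak was set against 10000 random lists matched on the length of sequence that would be assigned to each gene, in 10 bins (smallest possible p 0.0002). Six-to-eight-base words were searched on both strands within 100 bp of the summit and compared with windows centred 1000 bp to each side by exact McNemar tests. Benjamini-Hochberg adjustment was applied within each family. Replicates were compared by the overlap of at least 1 bp between their 311 strongest regions, and by ranks. For ranks, each optimal peak was matched to the region of largest overlap in each replicate's list, even where a stronger region overlapped it less. Confidence intervals are exact Clopper-Pearson intervals at 95%. Work was done in Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1.

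The designs, the gene lists, the words and the rule for naming genes were fixed before the data were examined. The gene lists were Hox genes and cofactors, vulval development, ventral cord motor neuron, Wnt pathway and Q neuroblast migration, programmed cell death, cell cycle, sex myoblast and M lineage, body wall muscle, epidermis and seam, intestine, pharynx, germline, stress response, ribosomal proteins, histones, homeobox ceh genes, nuclear hormone receptors, hlh genes and collagens. Of the listed symbols only lst-3 found no gene model. The rule named the genes at the 20 strongest peaks, up to 5 members with a peak per list, the genes with the most peaks, and lin-39, mab-5, ceh-13, egl-5 and unc-119. For the most peaks the rule asked for 3 genes, and 4 tied. Alternatives covered the build, a stricter signal threshold, overlap, promoter window, assignment limit, word window, Fisher's exact test, and using each replicate alone through its 311 strongest regions. Comparisons with other candidate regions were added after the data had been seen.

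The location, list and word tests were tested on simulated data made from 311 peaks placed at random on the real chromosomes. In 20 such sets with no effect, the promoter test made 0 calls, the list test 0 calls in 380 list tests and the word test 1 call. Peaks placed at random are not concentrated in promoters and intergenic sequence as the real peaks are. The rates of false calls of the list and word tests may therefore differ for the real peaks. All 20 sets with 60 peaks moved into promoters, with 7 peaks moved to genes of the Wnt list, or with 60 peaks moved onto GAGAGA were called. The ce10 lists were used only for the number of optimal peaks, the chromosome shares and the overlap between replicates.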

Results

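LIN-39 is the C. elegans Hox protein of the mid-body, where it is known to act in vulval precursor cells, ventral cord neurons and migrating neuroblasts. The data describe where its eGFP fusion was found on chromatin of whole L2 larvae, in 2 biological replicates. On ce11 the authors' optimal list held 311 peaks of 310 bp, and on ce10 it held 305. All 311 were the 311 strongest regions of the list called on both replicates together. The deposited signal value ran from 42.4 to 174.5 across them, with a median of 51.5. The q column stood at its highest value for 78 peaks. It corresponded to a nominal q of 0.05 or lower for 92 peaks, and the highest nominal q among the peaks was 0.441.

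Of the 20 strongest peaks 10 lay on X, and several lay more than 2000 bp from the nearest coding 5′ end. The first rank was at X:11094039-11094348 in intergenic sequence, 3992 bp from the 5′ end of W02H3.3, with a signal of 174.5 and ranks 3 and 1 in replicates 1 and 2. The second, at X:13700731-13701040 (signal 173.8, ranks 1 and 2), had no coding 5′ end within 5000 bp. The third was at X:9465719-9466028, 2529 bp from ZK899.6. Rank 4 was at II:10563406-10563715, 154 bp from the 5′ end of cdc-48.1, which encodes a AAA ATPase of protein quality control; its signal was 141.4 and its replicate ranks were 5 and 22. Rank 6, at X:8036246-8036555, had as its nearest 5′ end xol-1, the switch gene of sex determination and dosage compensation, at a distance of 4912 bp. Among the other strongest peaks, hel-1, a DEAD-box helicase gene, had rank 9 and rpl-15, which encodes a large-subunit ribosomal protein, rank 13. The rest of the 20 strongest were nearest F22H10.2, K12H4.5, tub-2, nspc-17, ZK1248.17, Y41G9A.17, K01F9.2, Y17G9B.5, T23G4.127 (at ranks 17 and 20), cest-16 and F55G7.5, and rank 14, at X:5429406-5429715, lay in coding sequence more than 5000 bp from any 5′ end.

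The first question was how far the 2 replicates gave the same sites. Of the 311 strongest regions of replicate 1, 137 (44.1%, 95% interval 38.5 to 49.8) overlapped one of the 311 strongest of replicate 2. Random placement of the second set gave 0.192% ± 0.251 (SD, 1000 placements; permutation p = 0.002, the smallest possible). Sharing was higher on X, with 42 of 73 regions (57.5%), than on the autosomes, with 95 of 238 (39.9%; Fisher's exact p = 0.0103, adjusted p = 0.0308 over 3 such splits, chosen after the data were seen). Almost every optimal peak was on both candidate lists (308 of 311), but only 132 were among the 311 strongest of both replicates, and 34 were in neither set. These counts use the rank of the region with the largest overlap, so part of the gaps in rank may come from the matching. Across the 308 matched peaks, the replicates' signal ranks had a Spearman rho of 0.208 (permutation p = 0.00022); this is across peaks, which are not independent replicates, in a set selected for high joint signal. Single loci differed widely: the peak at the 5′ end of egl-30, a Gq alpha subunit gene, had rank 4 in replicate 2 and rank 4717 in replicate 1.

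**Figure D1:**
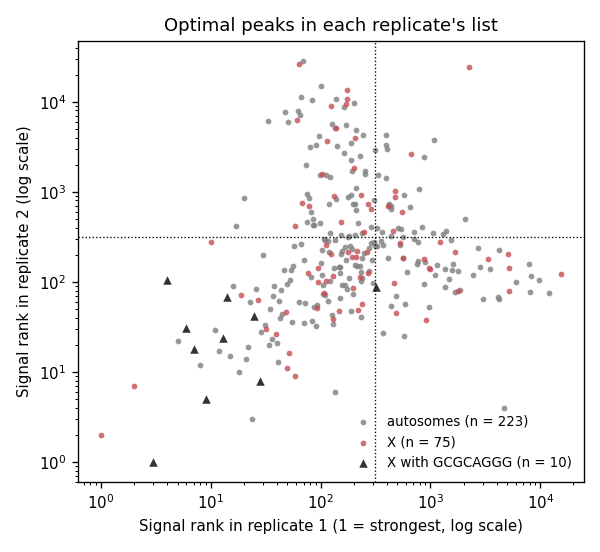
Signal rank of 308 optimal peaks in the candidate list of replicate 1 (x axis) and replicate 2 (y axis), both on log scales, with rank 1 the strongest; dotted lines mark rank 311. Grey points are autosomal peaks, red points X peaks and black triangles the 10 X peaks with GCGCAGGG near the summit, a word examined after the data were seen; many peaks within rank 311 of one replicate lie beyond it in the other.

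Peaks were more frequent than at random in promoters and in intergenic sequence, and less frequent in coding sequence. The promoter class overlaps the intergenic, intron, UTR and coding classes. Of the 311 summits, 139 (44.7%, 95% interval 39.1 to 50.4) were promoter-proximal, against 25.3% ± 2.46 (SD, 1000 placements) at random. Intergenic sequence held 204 summits (65.6%, random 37.4% ± 2.68) and coding sequence 7 (2.25%, random 24.2% ± 2.47). These 3 shares passed the permutation test (adjusted p = 0.0033). Introns held 89 summits (28.6%, random 33.9% ± 2.83, adjusted p = 0.0924) and UTRs 11 (3.54%, random 4.799% ± 1.21, adjusted p = 0.378), and neither passed the permutation test. The median distance to the nearest 5′ end was 1012 bp. On X, 27 of 86 summits were promoter-proximal (31.4%), against 49.8% of the 225 on the autosomes (Fisher's exact test, adjusted p = 0.0122 over 5 such tests, chosen after the data were seen). The median distance to a 5′ end was 1858 bp on X and 835 bp on the autosomes. Random shares were not taken for X and the autosomes apart, so a different density of 5′ ends on X is not separated from this gap.

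The peaks were spread unevenly over the chromosomes, with X over-represented. X carried 86 peaks (27.7%, 95% interval 22.8 to 33.0) for 17.7% of the sequence, 1.56 times its share by length (exact binomial test, adjusted p = 8.3e-05). Chromosome I carried 67 peaks (21.5%) for 15.03% of the sequence (exact binomial test, adjusted p = 0.0049), and V carried 38 (12.2%) for 20.9% (adjusted p = 0.00026). II, III and IV had 36, 41 and 43 peaks, 0.76, 0.96 and 0.79 times their share by length, and did not pass. In the 311 strongest regions of each replicate alone, X was also above its share by length in exact binomial tests, with 73 regions in replicate 1 (23.5%, adjusted p = 0.0275) and 85 in replicate 2 (27.3%, adjusted p = 0.000164). Chromosome I did not pass the exact binomial test in either replicate alone (adjusted p = 0.085 in replicate 1 and 0.319 in replicate 2), nor among the 156 peaks of higher signal (31 peaks, adjusted p = 0.14). By the same exact test V was low in replicate 1 (38 regions, adjusted p = 0.00052) but did not pass in replicate 2 (56 regions, adjusted p = 0.319), while IV was low in replicate 2 alone (36 regions, 0.66 times its share by length, adjusted p = 0.0167).

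**Figure D2:**
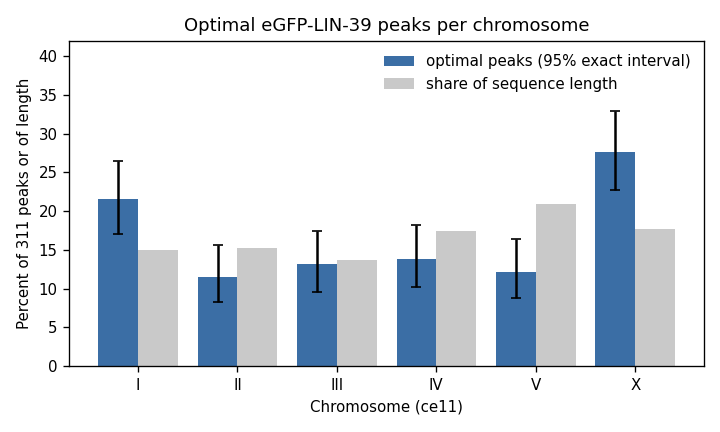
Percent of the 311 optimal peaks on each chromosome (blue bars, with 95% exact intervals) beside each chromosome's percent of sequence length (grey bars). X holds 27.7% of peaks for 17.7% of length, and V 12.2% for 20.9%.

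The next question was which genes lay nearest the peaks. In all, 289 peaks were assigned to 274 genes, 1.37% of coding genes, and 22 peaks had no 5′ end within 5000 bp. Of the 19 gene lists, 2 passed the test against territory-matched random lists with more members than matched lists, and 0 passed with fewer. No member of 10 lists had a peak.

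**Figure D3:**
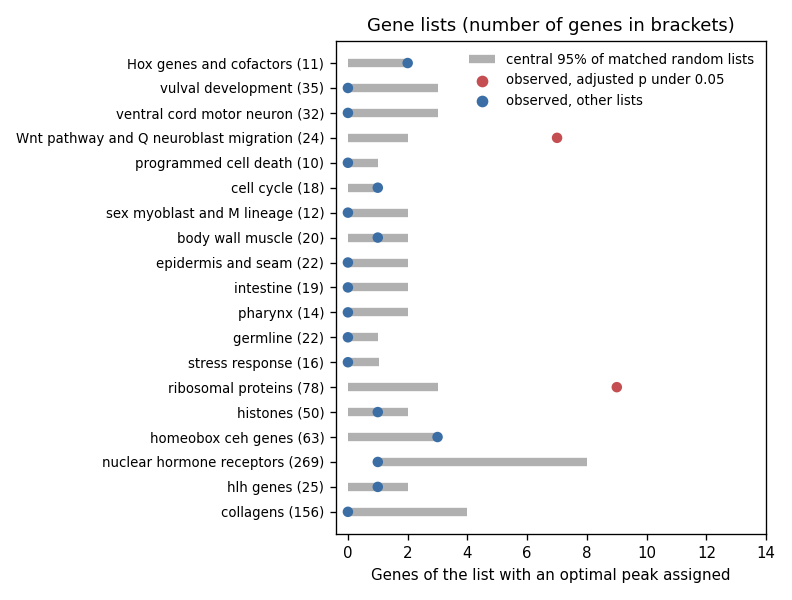
Number of genes of each list with an optimal peak assigned (points; red where the adjusted p was under 0.05), beside the central 95% of 10000 random lists matched on territory length (grey bars); the number of genes measured is in brackets. The Wnt pathway and Q neuroblast migration list has 7 of 24 genes and the ribosomal protein list 9 of 78, both beyond their matched lists.

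The first of these was the Wnt pathway and Q neuroblast migration list, with 7 of 24 members where matched lists had a mean of 0.617 (permutation test, adjusted p = 0.0019). The strongest peak was in an intron of egl-27, at II:6838239-6838548, with a signal of 93.9 and replicate ranks 16 and 89; EGL-27 is a chromatin protein of the MTA family. The next were in introns of unc-40, the netrin receptor gene (I:5690106-5690415, ranks 70 and 35), and cam-1, a Ror receptor kinase gene (II:9306966-9307275, ranks 50 and 95). The peak near mig-1, a Frizzled gene, had ranks 103 and 120 and lay 2551 bp from its 5′ end. The peak near pop-1, the TCF gene of the pathway, had rank 74 in replicate 1 and 2001 in replicate 2. With assignment limited to 2000 bp the list had 3 members with a peak and did not pass (permutation test, adjusted p = 0.12).

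The second was the ribosomal protein genes, of which 9 of 78 had a peak against 0.679 in matched lists (permutation test, adjusted p = 0.0019). These peaks lay close to 5′ ends. That of rpl-15 (IV:654765-655074, signal 116.5) was 344 bp away and had rank 15 in both replicates. Those of rpl-35, rpl-3 and rps-1 lay 466, 323 and 251 bp away, with signals of 97.1, 88.4 and 74.3. The rpl-12 peak, 39 bp away, had rank 20 in replicate 1 and 848 in replicate 2.

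No peak was assigned to any of the 35 vulval development genes or the 32 ventral cord motor neuron genes. Matched lists had means of 0.932 and 0.74, so at this number of peaks a count of 0 was within chance (permutation test, adjusted p = 1 for both). The vulval count depended on the replicate and the limit: 3 genes had one of the 311 strongest regions of replicate 1 (permutation test, adjusted p = 0.596) and 0 had one of replicate 2, and with a limit of 10000 bp 2 genes had an optimal peak (permutation test, adjusted p = 1). The programmed cell death (10 genes), sex myoblast and M lineage (12), epidermis and seam (22), intestine (19), pharynx (14), germline (22), stress response (16) and collagen (156) lists were also at 0. Their matched means were between 0.174 and 1.56, and none passed. The cell cycle list had 1 member with a peak, cki-1, a CDK inhibitor gene, at rank 309. Body wall muscle had unc-112, the kindlin gene, 374 bp from its 5′ end. Among gene families, the 63 ceh homeobox genes had 3 with a peak (ceh-38, ceh-5 and ceh-20), the 25 hlh genes had hlh-11, the 50 histone genes his-37, which belongs to a family of near-identical copies where read placement is uncertain, and the 269 nuclear hormone receptor genes nhr-3, where matched lists had a mean of 4.05 (permutation test, adjusted p = 0.72).

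On the list of Hox genes and cofactors, unc-62 and ceh-20 were the genes with a peak. The Meis-class gene unc-62 had 2 peaks, at V:4507828-4508137 (signal 78.0, ranks 37 and 69) and V:4508107-4508416 (signal 43.4, ranks 82 and 114), which overlap. The Pbx-class gene ceh-20 had 1, at III:6978982-6979291, 747 bp from its 5′ end. These were 2 of the 11 listed genes against 0.320 in matched lists, which did not pass (permutation test, adjusted p = 0.491). No optimal peak lay within 20 kb of lin-39 itself (III:7528641-7536632), mab-5, egl-5 or unc-119, the gene mutated in the strain background. The best candidate region in these windows had rank 4643 for lin-39, 388 for mab-5, 992 for egl-5 and 9299 for unc-119 of 30000. The lin-39 window held 5 candidate regions and the unc-119 window 8, against means of 12.3 and 11.9 in random windows of chromosome III (permutation p = 0.262 and 0.637). No excess of regions was thus detectable at either locus. One optimal peak, at III:7559937-7560246, lay within 20 kb of ceh-13, with ranks 75 and 933; its nearest 5′ end belonged to lgc-12.

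The most peaks per gene were 3, at T23G4.127 on IV, egl-30 and let-526 on I, and sma-9 on X. The gene let-526 encodes an ARID subunit of the SWI/SNF chromatin remodelling complex and sma-9 a Schnurri-type zinc finger protein of TGF-beta signalling. The 3 peaks of sma-9 had signals of 84.2, 51.2 and 43.5.

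The last question was which sequences marked the summits. The word GAGAGA was found within 100 bp of 140 of 311 summits (45.0%, 95% interval 39.4 to 50.7), against 14.1% and 13.5% in the flanks (exact McNemar test against the flank at higher coordinates, adjusted p = 3.2e-16, and against the other, 3.7e-17). It was as common at promoter-proximal summits (46.04%) as elsewhere (44.2%; Fisher's exact test, adjusted p = 0.819), with 41.9% on X and 46.2% on the autosomes (Fisher's exact test, adjusted p = 0.657). The Hox with Pbx consensus word TGATNNAT was found at 67 summits (21.5%, 95% interval 17.1 to 26.5), against 18.97% and 16.40% in the flanks, and did not pass against either (exact McNemar test, adjusted p = 0.72 and 0.20). The GATA-type word TGATAA was less frequent at summits (9.32%) than in the flanks (16.08% and 21.5%; exact McNemar test, adjusted p = 0.0372 and 9.7e-05). TAATTA, the homeodomain core, was at 5.47% of summits and 10.9% and 9.65% of flanks, a difference that passed against the first flank only (exact McNemar test, adjusted p = 0.0372 and 0.145). TGACTCA (3.22%) and CACGTG (4.82%) did not pass against either flank.

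**Figure D4:**
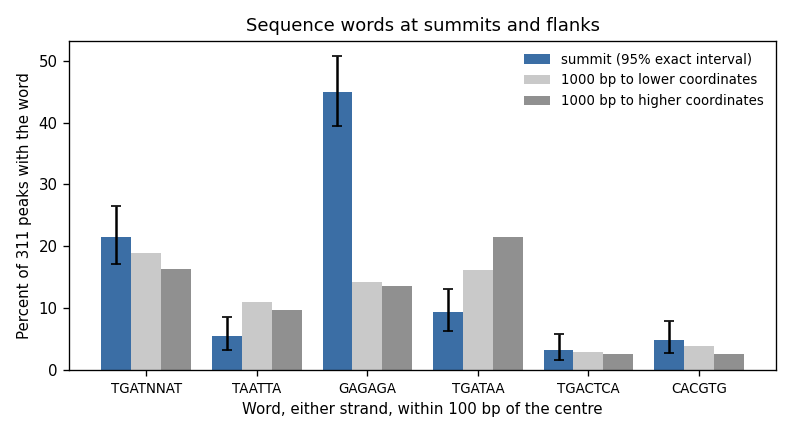
Percent of the 311 optimal peaks with each word within 100 bp of the summit (blue bars, with 95% exact intervals), and within 100 bp of points 1000 bp to lower (light grey) and higher (dark grey) coordinates. GAGAGA stands at 45.0% against 14.1% and 13.5%, and TGATAA at 9.32% against 16.08% and 21.5%.

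Neither word tracked the strength of a peak within the list. Peaks with TGATNNAT had a median signal rank of 148 and those without it 160 (permutation test, p = 0.587). Peaks with GAGAGA had a median rank of 157.5 and those without it 146 (permutation test, p = 0.543).

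**Figure D5:**
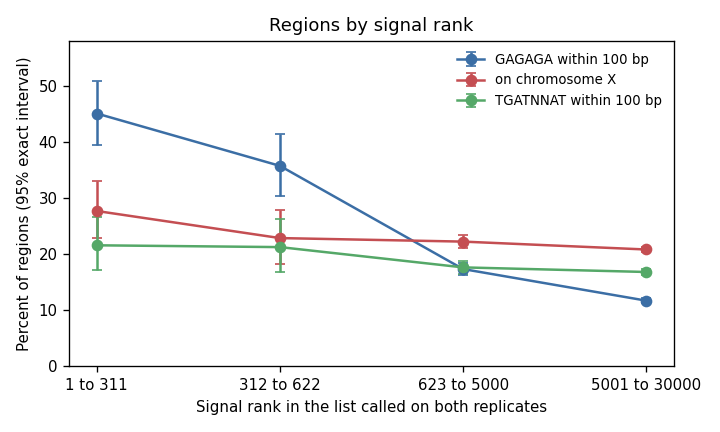
Percent of regions (y axis, with 95% exact intervals) that carry GAGAGA (blue) or TGATNNAT (green) within 100 bp of the summit, or lie on X (red), in 4 bands of signal rank of the list called on both replicates (x axis). GAGAGA goes from 45.0% in ranks 1 to 311 to 11.7% in ranks 5001 to 30000, while TGATNNAT goes from 21.5% to 16.8%.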

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

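The coverage-factor test on X, the word GCGCAGGG, the X excess without peaks that carry it and the comparison with other tissue lists were chosen only after the results they bear on had been seen. The overall share of GAGAGA among candidate regions had also been seen before the promoter test on that word was set.

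Candidate regions just outside the authors' threshold, which are not among the peaks, also carried GAGAGA. Of the 311 regions at ranks 312 to 622, 111 (35.7%, 95% interval 30.4 to 41.3) had GAGAGA within 100 bp of the summit, against 11.7% at ranks 5001 to 30000. There was no control library among the samples to set this against.

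GAGAGA at 45.0% of summits was weighed against 3 technical explanations. Promoter sequence in general is argued against, since promoter-proximal optimal peaks exceeded the 7806 promoter-proximal candidates below rank 622 by 31.8 percentage points. Reads piled on uninterrupted GA runs of 12 bp or more are argued against as the whole cause, since only 14 of the 311 peaks had such a run. Of the other 297 peaks, 42.4% carried the word (95% interval 36.7 to 48.3). With so few peaks to leave out, that share could not have come near the flanks. Shorter or imperfect repeats were not tested. One replicate alone is argued against too, the lower of the 2 replicates being at 38.6% of its 311 strongest regions. A candidate explanation that stays open, and was not tested because no other factor was among the samples, is that these are sites of open chromatin occupied by many factors and not specific to LIN-39.

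The excess on X was weighed next. A single coverage factor for the whole of X is argued against only if the signal value is proportional to coverage, which is not known. To bring X down to its share by length, signals on X would need dividing by 1.21 (bootstrap interval 1.10 to 1.38) at the optimal threshold. At the signal of the 5000th autosomal candidate the divisor would be 1.06 (1.05 to 1.08). A factor acting together with the GCGCAGGG sites described next was not tested. The word GCGCAGGG, part of the known consensus of sites that recruit the dosage compensation complex to X, was at 10 of 86 X peaks and 0 of 225 autosomal peaks, which allows up to 1.63% (Fisher's exact p = 1.8e-06), and at 7 of the 20 strongest peaks. The word was denser on X, at 4.57 occurrences per Mb against 2.82 on the autosomes. That density is argued against as the source of the word at the X peaks, since only 0.112% of the other X candidates carried it (95% interval 0.0451 to 0.231). Without the 10 peaks that carry the word, X still held 76 of 301 (25.2%, exact binomial p = 0.00109, adjusted p = 0.00219). Peaks with the exact word may thus account for the top of the list but not for the whole excess. With so few peaks to leave out, X could not have come down to its share by length. Sites with an imperfect match were not left out, so dosage compensation sites as a class stay open as a cause. General openness of such sites, or DNA from another immunoprecipitation, was not tested.

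The count of 0 for vulval and motor neuron genes among the optimal peaks was weighed against the height of the threshold; for the vulval list it was 3 in replicate 1 alone and 2 with a limit of 10000 bp. Among the 2000 strongest candidates, 19 of the 67 genes on these lists had a region, against 9.39 in matched lists (permutation p = 0.0024). A threshold that stops above weaker sites predicts such a rise. The 0 among the optimal peaks was itself within chance, with 1.65 in matched lists (permutation p = 0.366), so it needs no such account. Candidates below the optimal threshold may also be background. Whether the rise among the 2000 strongest candidates is particular to these lists stays open. The 97 genes of the muscle, epidermis, intestine, pharynx and germline lists had 17 against 9.58 (permutation p = 0.0252, added after the data were seen). A general rise of gene lists was to be excluded if at most 2 of the other 17 lists passed on their own, and 2 did, the Wnt and ribosomal lists. That bound proved to be wrong once the values were seen: the vulval list (10 of 35) and the motor neuron list (9 of 32) did not pass on their own either (permutation test, adjusted p = 0.202 and 0.165), so lists that do rise can be missed by it.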

How the results depend on the processing

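Comparisons with candidate regions, and with the flank at lower coordinates under these alternatives, were added after the data were seen. No result that passed its test changed direction under the alternatives run. Among the words compared with flanks, only TGATNNAT and GAGAGA were run under alternatives. The lower shares of TGATAA and TAATTA at summits were therefore not checked in this way. Keeping only peaks at or above the median signal left 156 peaks, against 311. Limiting assignment to 2000 bp left 1 list past the threshold, against 2: the Wnt list fell out, with 3 members and an adjusted p of 0.12, while its adjusted p was 4.6e-07 (Fisher's exact test) to 0.019 under the other alternatives; the ribosomal list had 9. TGATNNAT in a window of 200 bp (33.8% of summits) passed against the flank at higher coordinates (25.4%, exact McNemar test, adjusted p = 0.0494) but not against the other (31.5%, adjusted p = 0.845). It passed against random candidate regions (21.5% against 17.04%, permutation p = 0.04995), and the cause was not tested; it did not pass against either flank with 50 bp, the stricter signal or either replicate alone (adjusted p from 0.215 to 0.806). Windows of 40 kb around lin-39 and unc-119 held 1 optimal peak, against 0, and that around egl-5 held 2 (permutation p = 0.0804). The nearest 5′ ends of those 2 belonged to rpl-35 (rank 27) and ZK652.8 (rank 232), not to egl-5. Within 10 kb of lin-39 there were 0 candidate regions against 7.19 (permutation p = 0.0292). The X share was 27.5% on ce10, 30.8% with the stricter signal and 23.5% to 27.3% in 1 replicate alone. Only the 311 optimal peaks were tested against the 21.02% of X in the other candidates, which they exceeded (27.7%, exact binomial test, adjusted p = 0.0106). Chromosome I exceeded its share of those candidates by more, at 1.54 times (exact binomial test, adjusted p = 0.00091) against 1.32 times for X. V was low at 0.56 times (exact binomial test, adjusted p = 0.00011), but did not pass against length in replicate 2 alone. Chromosome I also passed against length on ce10 and without the peaks carrying GCGCAGGG (exact binomial test, adjusted p = 0.0026 and 0.0022). Chromosome I did not pass with the stricter signal or in either replicate alone (exact binomial test, adjusted p from 0.085 to 0.319), and IV passed as low in replicate 2 alone (adjusted p = 0.0167). The promoter share in 1 replicate alone was 41.2% to 43.7%, and that of GAGAGA 38.6% to 40.2%. Replicate overlap was 41.5% with reciprocal overlap of 50%, 52.9% for 155 regions, 30.7% for 622 and 44.1% on ce10. Of 133 list results under alternatives, 122 kept their direction and side of the threshold, and 10 changed direction, none past the threshold and with the cause not tested. The vulval list went from 0 to 2 with a limit of 10000 bp and 3 without replicate 2. The cell cycle list went from 1 to 0 with 2000 bp, with the stricter signal and without either replicate, hlh genes from 1 to 0 with the stricter signal, and histones from 1 to 0 without replicate 2. Epidermis and seam went from 0 to 1 without replicate 1, and body wall muscle had 1 against a mean of 1.13 from candidate regions. Outside the lists, chromosome III went from 0.96 to 1.29 times its share by length without replicate 2 and to 1.12 times its share of the other candidates, and the rank difference with GAGAGA from 11.5 to −2.5 with 200 bp. Nothing here gives read depth, and with 2 replicates and no other condition no paired or group test could be made.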

Other observations

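The tests on TGATNNAT by location, on tRNA genes and on chromosome centres were chosen after the data were seen.

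The 2000 strongest regions of the list called on both replicates were assigned to 1623 genes, 8.13% of coding genes. The vulval, motor neuron and body wall muscle lists did not pass against matched lists there (permutation test, adjusted p = 0.202, 0.165 and 0.165). On the Wnt and Q neuroblast list 12 of 24 genes had one, among them the 7 with optimal peaks; the other members were not tested by themselves. They included mom-5 at rank 414, mig-13, a gene of Q descendant migration, at rank 454, and bar-1, a beta-catenin gene, at rank 1085. On the vulval list the best ranks were those of sem-5 (471), lin-45 (702) and lin-31 (717), and egl-18, a GATA factor gene, had rank 1369. On the motor neuron list pag-3 had rank 434 and cfi-1 rank 826. Body wall muscle had 7 of 20 genes, with hlh-1 at rank 472 and unc-120 at rank 695, against 2.96 in matched lists. The ribosomal protein list had 15 of 78, the 9 with optimal peaks included. These genes outside the naming rule were chosen after their values were seen.

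Optimal peaks were also found beside tRNA genes and in chromosome centres. Of 311 summits, 7 (2.25%) lay within 200 bp of a tRNA gene, against 0.326% ± 0.312 at random (SD, 1000 placements) and 0.532% among other candidate regions (permutation p = 0.002 for both). On the autosomes 143 of 225 summits (63.6%) lay in the central 50% of their chromosome, against 49.9% ± 3.36 at random (permutation p = 0.002), but 59.7% of other candidate regions did so too (permutation p = 0.292). On X the central 50% held 43 of 86.

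The Hox with Pbx word was unevenly spread over the peaks. TGATNNAT was at 47 of 172 summits outside promoters (27.3%, 95% interval 20.8 to 34.6) and at 20 of 139 in promoters (14.4%; Fisher's exact p = 0.00809). Outside promoters it was above both flanks, at 17.4% and 13.95% (exact McNemar p = 0.0331 and 0.00379, adjusted p = 0.0663 and 0.0152 over the 2 classes and 2 flanks); in promoters it lay below both flanks, at 20.9% and 19.4%, and did not pass (exact McNemar p = 0.211 and 0.349). Part of the gap between the 2 groups of peaks may thus be a lower share at promoter summits, which the test outside promoters does not address. The split was found and tested on the same 311 peaks, so base composition around peaks outside promoters stays open as a cause, and no test here decides whether LIN-39 was bound through the word.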
